A study of Mus musculus with 12 samples.

How the data were processed

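Skin RNA of 12 mice was profiled by RNA sequencing, in 4 groups of 3: wild-type C57BL/6 or labelled IL-6 knockout, untreated or treated with BKC for 7 days. The groups and replicate numbers were taken from the sample titles. The treatment protocol speaks of 3 mice per group, so each library stands for a separate mouse. Per the sample records, RNA was isolated from skin with Tri-Reagent and libraries were made from total RNA with a TruSeq kit, and per the series design text they were sequenced on a MiSeq instrument. Strand-specific counting is not given in the sources used here, so reads of a gene and of an antisense gene over it cannot be told apart. The genome build was GRCm38 per the submitters' processing notes, and the aligner, counting program and annotation release are not given in the sources used here.

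Each deposited table lists, per the file headers, read counts per gene (unique and total exon reads, exon-exon junction reads, intron reads and gene reads), which are raw counts that were not normalised. The RPKM values, per the file headers reads scaled to exon length and library size, were deposited beside them and were used only to check the tables. They follow from the exon reads with a denominator that counts all gene reads in the untreated labelled-knockout tables and also reads outside genes in the other tables. A further column deposited by the authors, named per the file headers as an expression value, equals the exon reads in the untreated labelled-knockout tables and RPKM in the BKC tables, and in the untreated wild-type tables it differs from the other columns for part of the genes. It was not used. The groups were thus processed in 3 ways, untreated wild type, untreated labelled knockout and all BKC-treated libraries, which cannot be told apart from the groups themselves. Raw exon read counts do not depend on these denominators.

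The untreated tables list 49585 genes and those of BKC-treated skin list 51826, with exon lengths that differ for part of the genes, so that different gene models were used for the treatments. Only the 30709 genes with the same exon length above 0 in both were analysed, which kept 95.1% to 96.1% of exon reads, and 1352 shared genes with another exon length and 17452 with length 0 in the untreated tables were left out. A gene can still have gained or lost reads where a neighbouring model changed, and this stays confounded with treatment. The file of untreated wild-type replicate 1 holds 3 tables, of which the others are identical to the tables of replicates 2 and 3 in all 49585 genes, so only its first table was used. Counted exon reads ranged from 3675105 to 6602153 per library. At these depths 3 reads are worth 0.454 to 0.816 CPM in single libraries. Libraries of a group differed by far more than counting noise (chi-square per degree of freedom of at least 7.13), so none was counted as a repeat of another. The records do not say what the replicate numbers mark. Deviations from the group mean correlated at 0.273, 0.285 and 0.466 between same-number libraries of the wild-type groups, over 0.1 in 3 of 3 pairs. Elsewhere the lowest pair was at -0.0903 (BKC in labelled knockout), -0.130 (genotype untreated) and -0.0364 (genotype after BKC). Other-number pairs reached 0.165 in wild type and 0.518 between genotypes after BKC, so pairing is not shown.

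Total exon reads were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the groups, which left 13833, library sizes were scaled by TMM, and a quasi-likelihood model with 1 mean per group was fitted to all 12 libraries (glmQLFit and glmQLFTest, robust). The 5 comparisons were BKC against untreated in each genotype, labelled knockout against wild type in each treatment, and the interaction. P-values were adjusted by Benjamini-Hochberg over the tested genes, with 0.05 as the limit. The biological coefficient of variation was 0.286. The SE of a fold change is its size divided by the square root of the F statistic. CPM are TMM-normalised. Where a group had 0 reads a fold change is given as a bound against a floor of 3 counts over the group, and where it had 1 to 3 reads as a ratio with an exact 95% counting interval, both of which cover counting error only. Reads without molecular identifiers are not independent molecules.

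The 31 gene lists, with 614 genes of which 588 were among the genes used, were tested with camera (limma 3.58.1) at a correlation between genes of 0.01. The same test with an estimated correlation and the directional fry test were run beside it, all adjusted over the 31 lists within a comparison. Fry called 16.0, 17.0, 10.0, 1.0 and 12.0 lists in the 5 comparisons in the order above, where camera called 19.0, 21.0, 16.0, 16.0 and 14.0 and camera with an estimated correlation none. Whether genes within 20 Mb of Il6 were called more often between genotypes was tested with a one-sided Fisher's exact test. Positions come from the deposited tables, and exon overlaps from the GENCODE M21 annotation.

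The groups, the tests, the gene lists, the rule for named genes and the first set of alternatives were fixed before the data were examined. The rule named Il6 first, then the 6 genes with the highest and the 6 with the lowest fold changes in each BKC effect, and 5 and 5 in the genotype comparisons and the interaction, among called genes with a mean log2 CPM of at least 2 and groups that do not overlap, leaving out unnamed models. It also took up to 4 members of each list with the smallest adjusted p in the wild-type BKC effect, up to 2 in the genotype comparison after BKC, and 16 genes fixed by name, of which Il17a was not among the tested genes. Part of the genes so named are printed, and the others are not reported here. The alternatives chosen then were another scaling (DESeq2 1.42.0 size factors, or TMM without abundant, muscle and hair genes), no filter, DESeq2, limma-voom, only the groups compared, a replicate block, leaving out each library, a 2-fold limit, and a 10 Mb window. Another pseudocount had been foreseen for normalised values only and was not needed for counts. The alternatives added after the data were seen were uniquely placed reads, all shared genes with an exon length, the hair or muscle score as a covariate, all libraries thinned to the lowest depth, and the mean of both genotype contrasts for genes near Il6.

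The pipeline was tested on simulated counts drawn from the real means and depths with changed genes planted. At 4-fold, 83 of 100 changed genes were recovered for BKC in wild type (13624 genes) and 75 in labelled knockout (13648). Between genotypes 76 untreated and 78 after BKC of 100 were recovered (13617 and 13640), and 51 for the interaction (13634). At 2-fold these were 29 of 99, 20 of 99, 31 of 98, 35 of 100 and 4 of 99. False calls made up 2.80% to 6.06% of simulated calls. A list planted to rise was called all 5 times with no other. No simulated run tested correlated genes, so recovery in real libraries may be lower.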

Results

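RNA from the skin of 12 mice was sequenced in a model of irritant contact dermatitis, a skin inflammation caused by a chemical rather than by an allergy. The irritant was benzalkonium chloride (BKC), a quaternary ammonium detergent and antiseptic. The host factor was interleukin 6 (IL-6), a cytokine of inflammation. All mice, C57BL/6 wild type or labelled IL-6 knockout, were shaved. They were given 50 µl of 0.02% BKC for 7 days from 6 weeks of age or left untreated. BKC effects thus include any from the liquid and handling. Skin was taken on day 8, 3 mice per group. The libraries held 3675105 to 6602153 counted exon reads, so a read was worth 0.151 to 0.272 CPM, the read count scaled to library size. Untreated labelled-knockout libraries were the shallowest, at up to 4261220 reads. CPM are means ± SD over the 3 libraries of a group, and fold changes are log2 values ± SE with n = 3 mice per group.

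Il6, the gene targeted in the knockout (ENSMUSG00000025746), lies on chromosome 5, 30013114 to 30019981 (GRCm38), and its exons collected few reads. The untreated wild-type libraries held 2, 1 and 0 exon reads, and the untreated labelled-knockout libraries 6, 24 and 1. After BKC, wild-type skin held 7, 8 and 34 exon reads and labelled-knockout skin 25, 52 and 27. Il6 was thus not lower in the libraries labelled knockout. Untreated, it stood at 2.35 ± 2.60 CPM against 0.157 ± 0.158 in wild type, a ratio of 14.5-fold (95% counting interval 4.52 to 74.1). This difference was not past the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 0.0533). After BKC it stood at 6.63 ± 2.51 against 3.26 ± 3.42 CPM (log2 fold change 1.06 ± 0.82, adjusted p = 0.445). In wild-type skin Il6 was 18.0-fold (95% counting interval 5.82 to 90.5) higher after BKC (adjusted p = 0.0271). That call was lost without single libraries (adjusted p = 0.0539, 0.0729 and 0.0887 without wild-type untreated replicate 1, 2 or 3 and 0.0923 without wild-type BKC replicate 3). The tables give no reads per exon, so the disrupted part of the gene could not be looked at. An exchange of the genotype labels as a whole is not excluded by these reads, so the mice are called labelled knockout throughout and every direction between genotypes rests on these labels.

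The skin pieces differed in tissue makeup. Skeletal muscle genes, such as those of the sarcomere, took 9.79% ± 2.14 of counted reads in untreated wild-type skin, 1.59% ± 0.151 in untreated labelled-knockout skin, 1.5% ± 1.62 in BKC-treated wild-type skin and 5.18% ± 3.92 in BKC-treated labelled-knockout skin (SD, n = 3). Genes of the hair shaft and inner root sheath, made in growing follicles, took 0.0411% ± 0.0391, 6.20% ± 3.42, 0.897% ± 1.30 and 0.0227% ± 0.0152 in the same order. Within BKC-treated wild-type skin the hair share ran from 0.0157% to 2.39%.

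**Figure D1:**
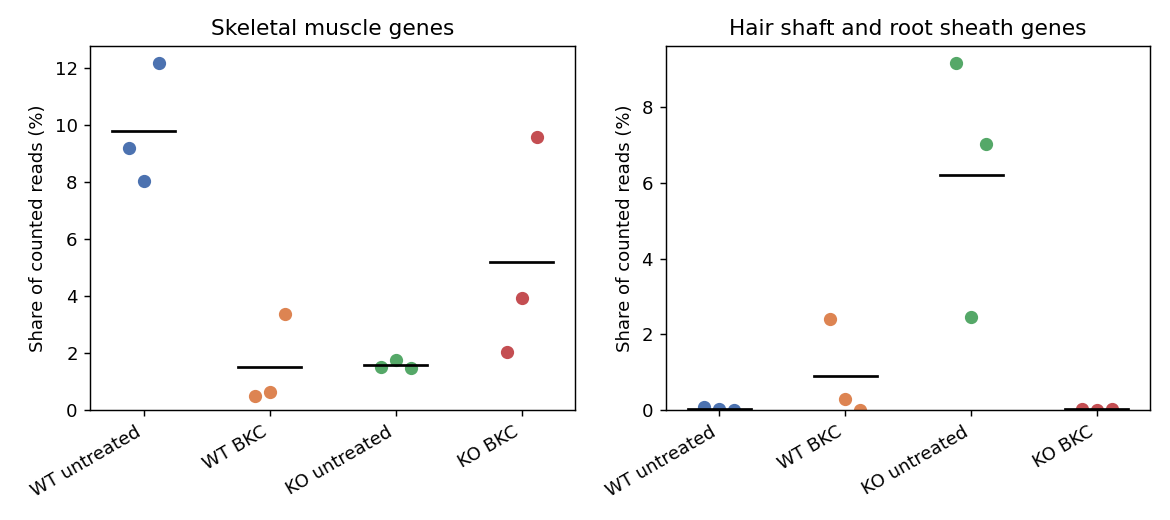
Share of counted reads (%) in skeletal muscle genes (left) and hair shaft and root sheath genes (right), 1 point per library and a line at the mean of each group of 3. WT is wild type and KO labelled knockout. Untreated wild-type libraries were the highest in muscle, with a mean of 9.79%, apart from 1 BKC-treated labelled-knockout library at 9.58%, and untreated labelled-knockout libraries were the highest in hair, with a mean of 6.20%.

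The first comparison asked how BKC changed wild-type skin. Keratins of wounded and fast-renewing epidermis rose. Krt6b went from 2.44 ± 2.14 to 10821 ± 4012 CPM (log2 fold change 12.07 ± 1.14, adjusted p = 0.000251) and Krt16 from 14.9 ± 9.39 to 7374 ± 2364 CPM (log2 fold change 8.95 ± 0.85, adjusted p = 0.000251). Genes of neutrophils rose as well, among them S100a9, a subunit of the antimicrobial protein calprotectin, from 1.16 ± 0.691 to 1569.6 ± 1389.9 CPM (log2 fold change 10.33 ± 1.12, adjusted p = 0.000271). Il1b, which encodes the inflammatory cytokine interleukin-1 beta, went from 0.361 ± 0.385 to 271 ± 68.5 CPM (log2 fold change 9.38 ± 1.25, adjusted p = 0.000714). The proliferation marker Mki67 went from 27.2 ± 5.29 to 201 ± 60.1 CPM (log2 fold change 2.88 ± 0.39, adjusted p = 0.000719). The muscle calcium-binding protein gene Pvalb fell, from 3119 ± 1578 to 123 ± 109 CPM (log2 fold change -4.67 ± 0.97, adjusted p = 0.00530), beside the lower muscle share of these libraries.

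In all, 5117 of 13833 genes passed the edgeR quasi-likelihood test at a Benjamini-Hochberg adjusted p of 0.05, 2926 of them higher and 2191 lower after BKC. These were 2586 and 2470 with TMM without abundant, muscle and hair genes and 2640 and 2441 with DESeq2 size factors. Of the 31 gene lists, 16.0 passed the camera test as higher and 3.0 as lower. None passed it with an estimated correlation between genes (lowest adjusted p = 0.160). Stress keratins rose in 4 of 4 cases (4 when adjusted over the list alone), with a median of 7.60, camera adjusted p = 2.81e-05 (0.181 with an estimated correlation). Krt6a stood at 6.24 ± 0.54 and Krt17 at 2.08 ± 0.31. Neutrophil genes rose in 17 of 17 cases (17 over the list alone), with a median of 7.30 (6.95 with genes at 0 reads at their bound), camera adjusted p = 4.17e-12 (0.312 with an estimated correlation). Acod1, the enzyme that makes itaconate in activated myeloid cells, was at least 325-fold higher (0 reads in untreated skin, floor of 3 counts over the group). Proliferation genes rose in 28 of 28 cases (28 over the list alone), with a median of 2.66, camera adjusted p = 1.98e-14 (0.344 with an estimated correlation). Birc5, the gene of survivin, stood at 2.85 ± 0.28. Small proline-rich and late cornified envelope genes, precursors of the cornified envelope, rose in 19 of 20 cases (19 over the list alone), with a median of 7.87 (7.67 with genes at 0 reads at their bound), camera adjusted p = 4.81e-16 (0.160 with an estimated correlation). Sprr1b went from 0.530 ± 0.302 to 979 ± 338 CPM. Sprr2i was at least 444-fold and Sprr2a1 at least 383-fold higher, although only 7.51% of Sprr2a1 reads were uniquely placed. Tmprss11b, a serine protease of stratified epithelia, was at least 436-fold higher.

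Alarmins and antimicrobial peptides rose in 14 of 16 cases and fell in 1 (14 over the list alone), with a median of 6.73 (5.67 with genes at 0 reads at their bound), camera adjusted p = 1.48e-09 (0.160 with an estimated correlation). S100a8 stood at 9.11 ± 1.08, the protease inhibitor Slpi at 8.27 ± 0.74 and the acute-phase gene Saa3 at 10.23 ± 1.02. Pro-inflammatory cytokines rose in 15 of 18 cases (15 over the list alone), with a median of 2.87, camera adjusted p = 2.96e-06 (0.413 with an estimated correlation). Chemokines rose in 12 of 29 cases and fell in 4 (12 over the list alone), with a median of 0.85, camera adjusted p = 0.00986 (0.659 with an estimated correlation). The neutrophil chemokine gene Cxcl2 was 3692-fold (95% counting interval 662 to 145867) higher, and Cxcl1 went from 0.271 ± 0.0704 to 8.73 ± 6.40 CPM. Wound repair genes rose in 23 of 29 cases and fell in 1 (25 over the list alone), with a median of 2.61, camera adjusted p = 7.93e-10 (0.344 with an estimated correlation). The growth factor gene Areg stood at 4.91 ± 0.45 and the matrix protein gene Tnc at 4.54 ± 0.47. Oxidative and xenobiotic stress genes rose in 16 of 24 cases and fell in 3 (16 over the list alone), with a median of 1.26, camera adjusted p = 0.00121 (0.181 with an estimated correlation). The cystine transporter Slc7a11 stood at 8.01 ± 0.63. Cholesterol biosynthesis genes rose in 16 of 25 cases (20 over the list alone), with a median of 0.78, camera adjusted p = 1.91e-05 (0.603 with an estimated correlation). Idi1 stood at 2.13 ± 0.24. Macrophage and monocyte genes rose in 8 of 18 cases (9 over the list alone), with a median of 0.99, camera adjusted p = 0.00219 (0.659 with an estimated correlation). As lists mast cell and basophil genes (median 1.21, camera adjusted p = 0.0306), interferon response genes (median 0.61, camera adjusted p = 0.0489) and immediate early genes (median 0.74, camera adjusted p = 0.0398) lay higher. With an estimated correlation none of them passed (lowest adjusted p of any list = 0.160).

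Genes of IL-6 and STAT3 signalling rose in 11 of 28 cases and fell in 2 (13 over the list alone), with a median of 0.65, camera adjusted p = 0.0165 (0.659 with an estimated correlation). The IL-4 receptor gene Il4ra (2.29 ± 0.31) and the metalloproteinase inhibitor Timp1 (3.39 ± 0.64) rose. Stat3 was at 174 ± 26.6 CPM untreated and 265 ± 32.7 after BKC (log2 fold change 0.61 ± 0.24, adjusted p = 0.0645). Its feedback inhibitor Socs3 was at 41.4 ± 14.2 and 99.1 ± 49.3 CPM (log2 fold change 1.26 ± 0.48, adjusted p = 0.0593). Hair genes rose in 19 of 33 cases (28 over the list alone), with a median of 4.66, camera adjusted p = 0.00206 (0.800 with an estimated correlation). Krt71, a keratin of the inner root sheath, did not pass (log2 fold change 4.63 ± 1.98, adjusted p = 0.0884). Skeletal muscle genes fell in 15 of 20 cases (17 over the list alone), with a median of -2.66, camera adjusted p = 3.68e-08 (0.516 with an estimated correlation). Adipocyte genes fell in 9 of 13 cases (12 over the list alone), with a median of -1.72, camera adjusted p = 5.19e-05 (0.516 with an estimated correlation). Schwann cell genes fell in 8 of 10 cases (9 over the list alone), with a median of -1.36, camera adjusted p = 9.45e-06 (0.160 with an estimated correlation). The myelin gene Prx fell (-2.61 ± 0.26). Muscle actin, Acta1, was at -2.32 ± 0.81 (adjusted p = 0.0442), while the fat hormone gene Adipoq did not pass (log2 fold change -1.40 ± 0.59, adjusted p = 0.0850).

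Among the largest falls were Skint7, of a family of epidermal immunoglobulin-like genes (-5.88 ± 0.78), the alcohol dehydrogenase Adh6a (-5.13 ± 0.75) and the ATP-gated channel P2rx2 (-5.06 ± 0.68). Angptl7 stood at -5.81 ± 0.52, with 23.8% of its reads uniquely placed. Usp50 was 93.7-fold (95% counting interval 25.6 to 779) lower, but 2.23% of its reads were uniquely placed. The tables of untreated and BKC-treated skin were made with different gene models, so the Usp50 value is uncertain. The basal keratin Krt14 rose (3.35 ± 0.44) and the barrier protein Flg was at 3.01 ± 1.04 (adjusted p = 0.0436). The differentiation keratin Krt10 was at 5561 ± 1398 and 6049 ± 3158 CPM (log2 fold change 0.12 ± 0.75, adjusted p = 0.912), and the cornified layer list did not pass (camera adjusted p = 0.802, adjusted p = 0.947 with an estimated correlation).

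The number of called genes in wild-type skin was 3321 with the hair score and 1948 with the muscle score as a covariate. It was 2917 without untreated replicate 3 and 3287 without BKC replicate 2. Without BKC replicate 3 the chemokine and the IL-6 and STAT3 lists were no longer called (adjusted p = 0.0547 and 0.0991), and without BKC replicate 1 the hair list (0.0696). The mast cell list was lost without a single library (0.0687 without wild-type BKC replicate 3). So was the interferon response list (0.277 without wild-type untreated replicate 2 and 0.0828 and 0.133 without wild-type BKC replicate 1 or 3) and the immediate early list (0.0513 without wild-type untreated replicate 1 and 0.0566 and 0.0590 without wild-type BKC replicate 1 or 2). In wild type with the hair score the hair (0.404) and immediate early (0.0635) lists were not called. That score added collagen and fibroblast (0.0425) and endothelial (0.0256) as higher. In wild type with the muscle score the cholesterol (0.736), hair (0.0998), skeletal muscle (0.732), mast cell (0.0580) and immediate early (0.902) lists were not called. That score added collagen and fibroblast (0.0184), endothelial (7.95e-05), erythroid cells (7.95e-05) and mitochondrially encoded (6.26e-05) as higher and cornified layer (1.28e-07) as lower. List calls also ended for interferon response (0.0606) with the replicate number as a block. Other lists passed as well, mitochondrially encoded as lower with no filter (0.0378), the replicate number as a block (0.0267), thinning (0.0483) and only the 2 groups fitted (0.0431). The call of Flg was lost without single libraries (adjusted p = 0.0867, 0.0968 and 0.141 without wild-type untreated replicate 1, 2 or 3 and 0.0968 and 0.118 without wild-type BKC replicate 1 or 2). It was also lost with the replicate number as a block (log2 fold change 2.73 ± 0.96 against 3.01 ± 1.04, adjusted p = 0.0513, range over the alternatives 0.00349 to 0.574). The call of Acta1 was lost without single libraries (0.0853 and 0.114 without wild-type untreated replicate 1 or 3 and 0.112 and 0.132 without wild-type BKC replicate 1 or 2).

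**Figure D2:**
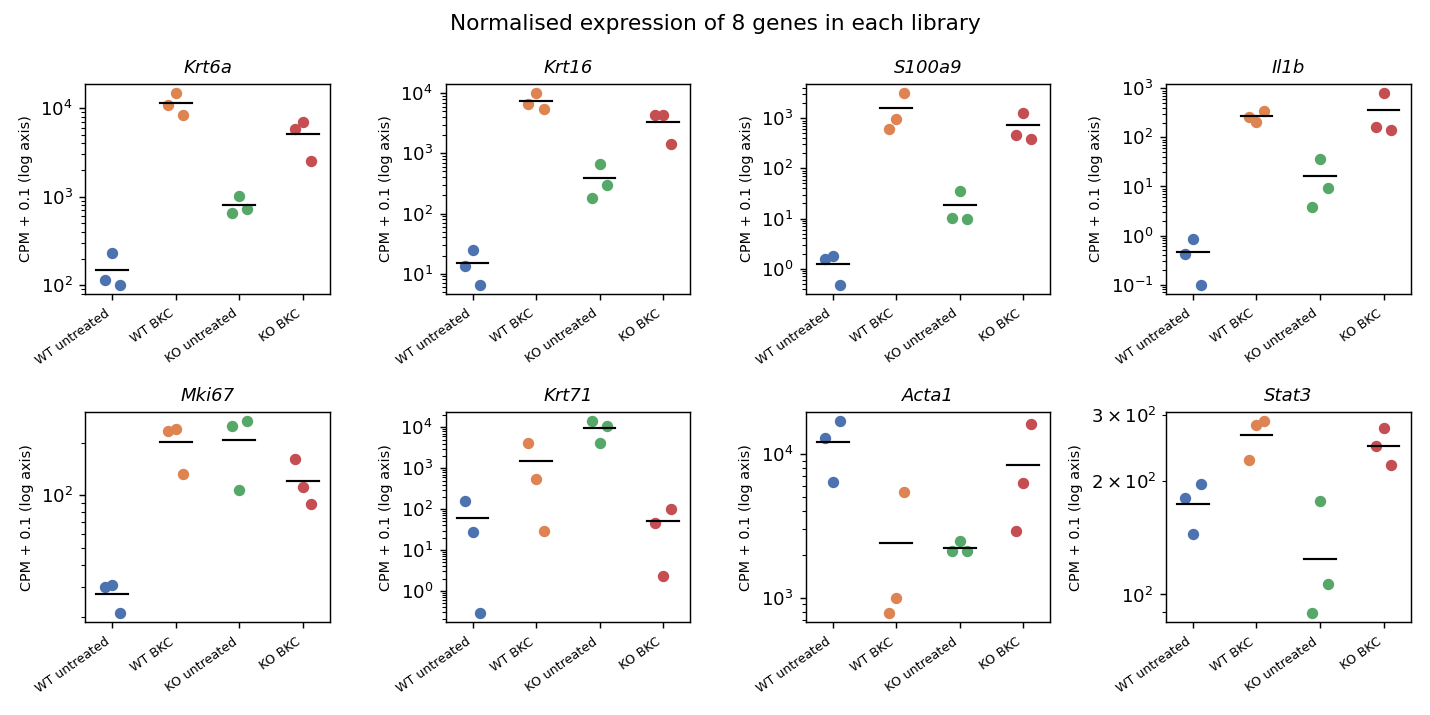
Normalised expression of 8 genes (CPM + 0.1, log axis), 1 point per library and a line at the mean of each group of 3. WT is wild type and KO labelled knockout. Krt6a, Krt16, S100a9 and Il1b lie higher after BKC in both genotypes, with Krt6a means of 149 and 11309 CPM in wild type and 801 and 5121 CPM in labelled knockout, while Mki67 differs between the untreated groups.

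The second comparison asked how BKC changed the skin of mice labelled IL-6 knockout. Neutrophil genes rose, with S100a9 going from 18.6 ± 14.9 to 718 ± 507 CPM (log2 fold change 5.26 ± 0.88, adjusted p = 0.00674). Il1b went from 16.1 ± 16.9 to 368 ± 371 CPM (log2 fold change 4.50 ± 0.91, adjusted p = 0.00914). Genes of blood vessels rose as well, with the vascular receptor Tie1 going from 14.7 ± 2.52 to 66.7 ± 12.2 CPM (log2 fold change 2.17 ± 0.23, adjusted p = 0.00283) and von Willebrand factor, Vwf, from 24.4 ± 6.38 to 141 ± 29.9 CPM (log2 fold change 2.53 ± 0.32, adjusted p = 0.00416). Hair shaft genes fell, beside a hair share that went from 6.20% to 0.0227% of reads. The keratin-associated protein genes Krtap14, Krtap19-9b, Krtap19-5, Krtap19-2, Krtap6-2 and Krtap19-1 had no read in the 3 BKC-treated libraries. They were at least 5594-fold, 1696-fold, 1610-fold, 1530.1-fold, 1275-fold and 714-fold lower, in this order, although no Krtap14 read was uniquely placed.

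The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment called 3599 of 13833 genes, 1786 higher and 1813 lower. Of the 31 lists, 16.0 passed camera as higher and 5.0 as lower, none of them with an estimated correlation (lowest adjusted p = 0.382). Neutrophil genes rose in 17 of 17 cases (17 over the list alone), with a median of 4.50, camera adjusted p = 5.03e-12 (0.382 with an estimated correlation). Endothelial genes rose in 15 of 16 cases (16 over the list alone), with a median of 1.71, camera adjusted p = 1.70e-11 (0.382 with an estimated correlation). Hair genes fell in 33 of 33 cases (33 over the list alone), with a median of -8.06 (-8.05 with genes at 0 reads at their bound), camera adjusted p = 1.30e-16 (0.427 with an estimated correlation). Wound repair genes rose in 22 of 29 cases and fell in 1 (26 over the list alone), with a median of 1.87, camera adjusted p = 1.79e-10 (0.382 with an estimated correlation). Collagen and fibroblast genes rose in 13 of 18 cases (16 over the list alone), with a median of 1.72, camera adjusted p = 2.16e-07 (0.455 with an estimated correlation). The matrix protein gene Fbln2 went from 156 ± 80.7 to 778 ± 164 CPM. Alarmins and antimicrobial peptides rose in 12 of 16 cases and fell in 1 (13 over the list alone), with a median of 3.06, camera adjusted p = 9.46e-06 (0.382 with an estimated correlation). Small proline-rich and late cornified envelope genes rose in 15 of 20 cases and fell in 1 (17 over the list alone), with a median of 2.76, camera adjusted p = 9.06e-08 (0.382 with an estimated correlation). Pro-inflammatory cytokines rose in 9 of 18 cases (12 over the list alone), with a median of 1.85, camera adjusted p = 2.15e-06 (0.449 with an estimated correlation). Chemokines rose in 10 of 29 cases (11 over the list alone), with a median of 1.32, camera adjusted p = 8.86e-05 (0.455 with an estimated correlation). Macrophage and monocyte genes rose in 9 of 18 cases (16 over the list alone), with a median of 1.61, camera adjusted p = 2.63e-05 (0.455 with an estimated correlation). As lists skeletal muscle genes (median 1.89, camera adjusted p = 0.00232), Schwann cell genes (median 0.90, camera adjusted p = 0.0105) and mitochondrially encoded genes (median 0.74, camera adjusted p = 0.0301) lay higher. As lists sebaceous gland and fatty acid synthesis genes (median -0.48, camera adjusted p = 0.0268) lay lower. None of these passed with an estimated correlation (lowest adjusted p of any list = 0.382).

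Among the largest rises, the chemokine Cxcl5 was 163-fold (95% counting interval 55.5 to 792) and the regenerating-family gene Reg1 257-fold (95% counting interval 45.8 to 10193) higher. Saa3 stood at 6.52 ± 0.82, Cxcl3 at 6.45 ± 0.93 and the myeloid receptor Cd300lf at 5.33 ± 0.82 (29.1% of its reads uniquely placed). Stress keratins rose in 3 of 4 cases (3 over the list alone), with a median of 2.91, camera adjusted p = 0.0482 (0.489 with an estimated correlation). Krt6a stood at 2.68 ± 0.46 and Krt16 at 3.14 ± 0.65, while Krt17 did not pass (log2 fold change -0.70 ± 0.30, adjusted p = 0.103). No proliferation gene passed on its own, Mki67 included (log2 fold change -0.78 ± 0.36, adjusted p = 0.130), while the list lay lower at a median of -0.51. The proliferation list had a camera adjusted p = 0.00831 (0.610 with an estimated correlation). Melanocyte genes fell in 8 of 9 cases (8 over the list alone), with a median of -4.0, camera adjusted p = 0.000296 (0.455 with an estimated correlation). The pigment enzyme Tyrp1 stood at -4.22 ± 0.73. Cholesterol biosynthesis genes fell in 5 of 25 cases and rose in 1 (5 over the list alone), with a median of -0.49, camera adjusted p = 0.00309 (0.603 with an estimated correlation). Genes of IL-6 and STAT3 signalling rose in 10 of 28 cases and fell in 3 (12 over the list alone), with a median of 0.76, camera adjusted p = 0.00560 (0.549 with an estimated correlation). Stat3 stood at 1.00 ± 0.24 (adjusted p = 0.0150) and Socs3 at 1.78 ± 0.49 (adjusted p = 0.0241). Usp50 was 179.6-fold (95% counting interval 31.7 to 7139) lower here too, with the same doubt as in wild type.

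With the hair score as a covariate edgeR called 0 genes for BKC in labelled knockout, with 939 at an unadjusted p under 0.05. Without that covariate DESeq2 called 4417 and limma-voom 3361, and with the muscle score edgeR called 2348. The count was 1364 without untreated replicate 1, 1396 without untreated replicate 3, 1819 without BKC replicate 2 and 2043 without BKC replicate 3. The stress keratin list lost its call without single libraries (adjusted p = 0.0891 and 0.0541 without labelled-knockout untreated replicate 2 or 3 and 0.0933 and 0.0816 without labelled-knockout BKC replicate 1 or 2). For labelled knockout with the hair score the proliferation (0.344), chemokine (0.146), IL-6 and STAT3 (0.826), cholesterol (0.452), sebaceous gland (0.0572), hair (0.558), melanocyte (0.0712) and mitochondrially encoded (0.0814) lists were not called, and the skeletal muscle (0.00600) list was called in the other direction. That score added cornified layer (6.14e-06) as higher and erythroid cells (0.0106) as lower. For labelled knockout with the muscle score the proliferation (0.507), cholesterol (0.203), skeletal muscle (0.488) and mitochondrially encoded (0.841) lists were not called. That score added cornified layer (0.00125) and T and NK cell (0.0258) as higher. List calls also ended for mitochondrially encoded (0.461) with uniquely placed reads, and stress keratin (0.0602) and sebaceous gland (0.0555) with only the 2 groups fitted. Other lists passed as well, type 2 immunity (0.0469), T and NK cell (0.0122) and mast cell (0.0469) as higher with no filter. The proliferation list was lost without single libraries as well (adjusted p = 0.0941 and 0.0724 without labelled-knockout untreated replicate 1 or 3 and 0.148 without labelled-knockout BKC replicate 3). So were the skeletal muscle list (0.0676 without labelled-knockout BKC replicate 3), the Schwann cell list (0.0550 without labelled-knockout untreated replicate 2) and the sebaceous gland list (0.135 without labelled-knockout untreated replicate 2 and 0.0546 without labelled-knockout BKC replicate 2). The mitochondrially encoded list was lost too (0.0872 and 0.0724 without labelled-knockout untreated replicate 2 or 3 and 0.0610 and 0.218 without labelled-knockout BKC replicate 2 or 3). So were the IL-6 and STAT3 list (0.0546 without labelled-knockout BKC replicate 2), the cholesterol list (0.0865 without labelled-knockout BKC replicate 3), Stat3 (0.0587 and 0.0577 without labelled-knockout untreated replicate 1 or 3) and Socs3 (0.0954 and 0.0848 without labelled-knockout untreated replicate 1 or 3 and 0.0810 without labelled-knockout BKC replicate 2).

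The third comparison asked how untreated skin differed with genotype. Hair genes were higher in labelled-knockout skin, with Krt71 at 9724 ± 5015 against 62.3 ± 85.4 CPM (log2 fold change 7.28 ± 2.24, adjusted p = 0.0340). Mki67 was higher, at 206 ± 86.8 against 27.2 ± 5.29 CPM (log2 fold change 2.92 ± 0.39, adjusted p = 0.00266). Krt6a was higher, at 801 ± 188 against 149 ± 71.5 CPM (log2 fold change 2.42 ± 0.45, adjusted p = 0.00533). The fast myosin gene Myh4 was lower, at 656 ± 299.9 against 18591 ± 5237 CPM (log2 fold change -4.83 ± 1.14, adjusted p = 0.0127). These differences stood beside a hair share of 6.20% against 0.0411% of reads. The muscle share was 1.59% against 9.79%.

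The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment called 4126 genes, 2476 higher and 1650 lower in the libraries labelled knockout. These were 2182 and 1853 with TMM without abundant, muscle and hair genes, 1909 and 1805 with thinning and 1978 and 1878 with only the 2 groups fitted. Hair genes were higher in 33 of 33 cases (33 over the list alone), with a median of 7.62, camera adjusted p = 1.10e-13 (0.670 with an estimated correlation). Proliferation genes were higher in 27 of 28 cases (28 over the list alone), with a median of 2.33, camera adjusted p = 1.10e-13 (0.641 with an estimated correlation). Stress keratins were higher in 4 of 4 cases (4 over the list alone), with a median of 3.56, camera adjusted p = 0.000504 (0.542 with an estimated correlation). Skeletal muscle genes were lower in 16 of 20 cases (18 over the list alone), with a median of -2.64, camera adjusted p = 3.15e-07 (0.676 with an estimated correlation). Small proline-rich and late cornified envelope genes were higher in 16 of 20 cases (18 over the list alone), with a median of 4.17 (4.04 with genes at 0 reads at their bound), camera adjusted p = 1.78e-08 (0.542 with an estimated correlation). Alarmins and antimicrobial peptides were higher in 8 of 16 cases (8 over the list alone), with a median of 3.17 (2.52 with genes at 0 reads at their bound), camera adjusted p = 0.00296 (0.672 with an estimated correlation). Melanocyte genes were higher in 8 of 9 cases (8 over the list alone), with a median of 4.55, camera adjusted p = 0.000503 (0.676 with an estimated correlation). Cholesterol biosynthesis genes were higher in 11 of 25 cases (12 over the list alone), with a median of 0.53, camera adjusted p = 0.00190 (0.831 with an estimated correlation). Endothelial genes were lower in 13 of 16 cases (13 over the list alone), with a median of -1.16, camera adjusted p = 3.15e-07 (0.641 with an estimated correlation). Schwann cell genes were lower in 6 of 10 cases (6 over the list alone), with a median of -1.40, camera adjusted p = 0.000114 (0.361 with an estimated correlation). Adipocyte genes were lower in 4 of 13 cases (6 over the list alone), with a median of -1.31, camera adjusted p = 0.000379 (0.676 with an estimated correlation). Mitochondrially encoded genes lay lower as a list, with 1 of 13 past the test and a median of -0.73. The mitochondrially encoded list had a camera adjusted p = 0.00761 (0.831 with an estimated correlation). They took 4.54% ± 0.266 of reads against 7.21% ± 1.85 in wild type (SD), a share that depends on tissue and RNA quality. As lists wound repair genes (median 0.86, camera adjusted p = 0.0343) and neutrophil genes (median 3.30, camera adjusted p = 0.00369) lay higher. As lists dendritic and Langerhans cell genes (median -0.64, camera adjusted p = 0.0294) and collagen and fibroblast genes (median -0.51, camera adjusted p = 0.0483) lay lower. With an estimated correlation no list passed between untreated genotypes (lowest adjusted p = 0.361). The mitochondrially encoded list lost its call without a single library (adjusted p = 0.0700 without wild-type untreated replicate 3). So did the wound repair list (0.0646 without wild-type untreated replicate 2 and 0.464 without labelled-knockout untreated replicate 2) and the neutrophil list (0.0776 without labelled-knockout untreated replicate 2). The dendritic cell list did as well (0.0644 without wild-type untreated replicate 1 and 0.106 and 0.0778 without labelled-knockout untreated replicate 1 or 3), and the collagen and fibroblast list (0.402 and 0.0667 without wild-type untreated replicate 1 or 3 and 0.381 and 0.0639 without labelled-knockout untreated replicate 1 or 3). Untreated, with the hair score the collagen and fibroblast (0.974), cholesterol (0.144), hair (0.412), skeletal muscle (0.353), dendritic cell (0.299) and mitochondrially encoded (0.597) lists were not called. That score added cytokine (0.00623), chemokine (0.000904), IL-6 and STAT3 (0.00909), oxidative stress (0.00427), macrophage (0.00387) and erythroid cells (0.00806) as higher and cornified layer (0.000904) and basal keratinocyte (0.0391) as lower. Untreated, with the muscle score the collagen and fibroblast (0.653), cholesterol (0.807), skeletal muscle (0.743) and dendritic cell (0.277) lists were not called, and the mitochondrially encoded (0.0201) list was called in the other direction. That score added oxidative stress (0.0355), macrophage (0.00341) and erythroid cells (2.22e-05) as higher and cornified layer (3.99e-07), basal keratinocyte (0.000299) and T and NK cell (0.0117) as lower. List calls also ended for collagen and fibroblast with DESeq2 size factors (0.0532), TMM without abundant, muscle and hair genes (0.0596), the replicate number as a block (0.0703), uniquely placed reads (0.0516), thinning (0.0515) and only the 2 groups fitted (0.125), and mitochondrially encoded (0.842) with uniquely placed reads, and neutrophil (0.0679) and dendritic cell (0.0688) with only the 2 groups fitted. Other lists passed as well, immediate early as higher with no filter (0.0371), the replicate number as a block (0.0470) and only the 2 groups fitted (0.0466).

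Among the keratin-associated genes Krtap19-9a was at least 499-fold higher, Krtap19-2 stood at 9.53 ± 1.79 and Krtap19-3 at 9.20 ± 1.77. Krtap19-1 was 2493-fold (95% counting interval 447 to 98519) higher and Krtap19-4 795-fold (95% counting interval 219 to 6570.3). S100a9 stood at 3.94 ± 0.92, Slc7a11 at 5.89 ± 0.64 and Vwf at -1.49 ± 0.31, while Il1b stood at 5.32 ± 1.2 (adjusted p = 0.0106). Among the largest falls were Lrrc14b (-4.93 ± 1.27), whose reads were uniquely placed in 6.57% of cases, and the phosphatase Dusp26 (-4.54 ± 0.62). AI506816, a gene of unknown function, stood at -4.12 ± 0.44 (adjusted p = 0.00244).

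With the hair score as a covariate edgeR called 0 genes between untreated genotypes, with 1417 at an unadjusted p under 0.05. Without that covariate DESeq2 called 4883 and limma-voom 3911, and with the muscle score edgeR called 192. The count was 1736 without wild-type replicate 3, 2646 without wild-type replicate 1, 1839 without labelled-knockout replicate 1 and 1761 without labelled-knockout replicate 3. Krt71 lost its call without single libraries (adjusted p = 0.0935 and 0.0748 without wild-type untreated replicate 2 or 3 and 0.0766 and 0.0747 without labelled-knockout untreated replicate 1 or 3). So did S100a9 (0.0535 without wild-type untreated replicate 3), Lrrc14b (0.0535 without wild-type untreated replicate 3 and 0.0594 and 0.0701 without labelled-knockout untreated replicate 1 or 3) and Myh4 (0.0558 without labelled-knockout untreated replicate 3).

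The fourth comparison asked how BKC-treated skin differed with genotype. Only AI506816 and Elovl3, an enzyme of fatty acid elongation in sebaceous glands, were called among 13833 genes by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. AI506816 (ENSMUSG00000105987, chromosome 5, 23698296 to 23712667) was lower in labelled knockout, at 1.24 ± 0.933 against 186 ± 17.9 CPM (log2 fold change -7.17 ± 0.48, adjusted p = 0.000245). Elovl3 (ENSMUSG00000038754, chromosome 19, 46131897 to 46135307) was lower, at 6.87 ± 0.508 against 32.7 ± 5.46 CPM (log2 fold change -2.25 ± 0.25, adjusted p = 0.0182). The inflammatory genes S100a9 and Il1b were not past the test, which does not show that they were alike, and lists of inflammatory genes are given below. S100a9 stood at 718 ± 507 against 1569.6 ± 1389.9 CPM (log2 fold change -1.13 ± 0.73, adjusted p = 0.367) and Il1b at 368 ± 371 against 271 ± 68.5 CPM (log2 fold change 0.44 ± 0.78, adjusted p = 0.748). Krt6a stood at 5121 ± 2319.9 against 11309 ± 3205 CPM (log2 fold change -1.14 ± 0.43, adjusted p = 0.173).

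At an unadjusted p under 0.05 there were 3089 genes, DESeq2 called 967 and limma-voom 1. As whole lists, with 0 members past the test over all genes, hair genes lay lower in labelled-knockout skin (33 of 33 over the list alone, median -5.38, or -5.34 with genes at 0 reads at their bound). The hair list had a camera adjusted p = 2.90e-09 (0.661 with an estimated correlation). Cholesterol genes lay lower (15 of 25 over the list alone, median -0.67). The cholesterol list had a camera adjusted p = 1.78e-09 (0.661 with an estimated correlation). Proliferation genes lay lower (5 of 28 over the list alone, median -0.80). The proliferation list had a camera adjusted p = 6.94e-09 (0.661 with an estimated correlation). Muscle genes lay higher (0 of 20 over the list alone, median 1.79), beside a muscle share of 5.18% against 1.5%. The skeletal muscle list had a camera adjusted p = 2.77e-08 (0.661 with an estimated correlation). Schwann cell genes lay higher (8 of 10 over the list alone, median 0.89). The Schwann cell list had a camera adjusted p = 1.54e-06 (0.130 with an estimated correlation). The IL-6 and STAT3 list did not pass (camera adjusted p = 0.837, adjusted p = 0.945 with an estimated correlation, 0 members over the list alone).

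The following lists had 0 members past the test over all genes. As lists macrophage and monocyte genes (median 0.66, camera adjusted p = 0.0110), dendritic and Langerhans cell genes (median 0.73, camera adjusted p = 1.74e-05), interferon response genes (median 0.31, camera adjusted p = 0.0425), endothelial genes (median 0.34, camera adjusted p = 0.00255) and collagen and fibroblast genes (median 0.77, camera adjusted p = 0.00143) lay higher. As lists stress keratins (median -1.13, camera adjusted p = 0.02), alarmins and antimicrobial peptides (median -0.92, camera adjusted p = 0.0145), small proline-rich and late cornified envelope genes (median -0.81, camera adjusted p = 0.00106), basal keratinocyte genes (median -0.61, camera adjusted p = 0.0145), oxidative and xenobiotic stress genes (median -0.31, camera adjusted p = 0.0373) and mast cell and basophil genes (median -0.61, camera adjusted p = 0.0237) lay lower. With an estimated correlation no list passed after BKC (lowest adjusted p = 0.130).

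Without wild-type replicate 3 the count was 1123, and it was 1 without any of the other 5 libraries. It was 0 when only these 6 libraries were fitted. The call lost was that of Elovl3 (adjusted p = 0.0588 and 0.0765 without wild-type BKC replicate 1 or 2 and 0.116, 0.190 and 0.243 without labelled-knockout BKC replicate 1, 2 or 3). With the replicate number as a block 2 genes were called, of which 1 was shared, and Elovl3 was not called (log2 fold change -2.24 ± 0.27 against -2.25 ± 0.25, adjusted p = 0.0713, range over the alternatives 1.86e-09 to 0.243). Its fold was nearly the same there, with a larger error and fewer residual degrees of freedom. Several lists lost their call without single libraries, stress keratins (adjusted p = 0.0622 without labelled-knockout BKC replicate 3), alarmins (0.234 without wild-type BKC replicate 3) and small proline-rich genes (0.0597 without labelled-knockout BKC replicate 3). So did basal keratinocytes (0.0743 without labelled-knockout BKC replicate 3), macrophages (0.0537 without wild-type BKC replicate 2) and mast cells (0.120 without wild-type BKC replicate 3). The interferon list did as well (0.285 and 0.0692 without wild-type BKC replicate 2 or 3 and 0.174 and 0.115 without labelled-knockout BKC replicate 1 or 3), and the oxidative stress list (0.137 without wild-type BKC replicate 3 and 0.172 and 0.0743 without labelled-knockout BKC replicate 1 or 3). After BKC with the hair score the stress keratin (0.0602), interferon response (0.352), collagen and fibroblast (0.0921), hair (0.207), macrophage (0.227) and endothelial (0.748) lists were not called. That score added cornified layer (0.000839) as higher and cytokine (0.0403) and IL-6 and STAT3 (0.0242) as lower. After BKC with the muscle score the stress keratin (0.433), small proline-rich (0.242), basal keratinocyte (0.598), interferon response (0.598), collagen and fibroblast (0.152), hair (0.0696), skeletal muscle (0.350), macrophage (0.471) and endothelial (0.849) lists were not called. That score added cornified layer (6.66e-13) as higher and erythroid cells (5.15e-05) and mitochondrially encoded (9.84e-05) as lower. List calls also ended for oxidative stress with uniquely placed reads (0.0655), all shared genes with an exon length (0.0540) and thinning (0.0542), and interferon response (0.0728) with the replicate number as a block. Other lists passed as well, mitochondrially encoded (0.0303) as higher with the replicate number as a block, and melanocyte (0.0419) as lower with only the 2 groups fitted.

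The interaction asked whether the BKC effect itself differed between genotypes, as the effect in labelled knockout minus that in wild type. Mki67 had a lower effect in labelled knockout, -0.78 ± 0.36 against 2.88 ± 0.39 (interaction -3.66 ± 0.53, adjusted p = 0.00317). Krt6a had 2.68 ± 0.46 against 6.24 ± 0.54 (interaction -3.57 ± 0.62, adjusted p = 0.00372), where the untreated level was already higher in labelled knockout. Myh4 had 3.81 ± 1.09 against -3.70 ± 1.08 (interaction 7.51 ± 1.53, adjusted p = 0.00609). The BKC calls of Myh4 were lost without single libraries, in labelled knockout (adjusted p = 0.0727, 0.0578 and 0.0995 without labelled-knockout untreated replicate 1, 2 or 3 and 0.0861 without labelled-knockout BKC replicate 3) and in wild type (0.0584 without wild-type untreated replicate 3 and 0.0781 without wild-type BKC replicate 2).

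The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment called 4839 genes for the interaction, 2037 with a higher and 2802 with a lower effect in the libraries labelled knockout. Of these, 3494 (72.2%) were also called between genotypes in untreated skin, where independent lists of these sizes would share 1443. Both contrasts use the untreated libraries. Lists of these sizes from 10 simulations without any difference shared 2446 to 2499, which does not give the part of the real overlap due to these libraries. Hair genes differed downward in 33 of 33 cases (33 over the list alone), camera adjusted p = 1.68e-13 (0.539 with an estimated correlation). Proliferation genes differed downward in 28 of 28 cases (28 over the list alone), with a median of -3.19, camera adjusted p = 1.68e-13 (0.539 with an estimated correlation). Stress keratins differed downward in 4 of 4 cases (4 over the list alone), with a median of -4.69, camera adjusted p = 0.00107 (0.539 with an estimated correlation). Small proline-rich genes differed downward in 17 of 20 cases (18 over the list alone), camera adjusted p = 2.96e-08 (0.539 with an estimated correlation). Cholesterol biosynthesis genes differed downward in 19 of 25 cases (20 over the list alone), with a median of -1.22, camera adjusted p = 1.28e-06 (0.539 with an estimated correlation). Skeletal muscle genes differed upward in 18 of 20 cases (19 over the list alone), with a median of 4.42, camera adjusted p = 2.03e-08 (0.539 with an estimated correlation). Endothelial genes differed upward in 13 of 16 cases (13 over the list alone), with a median of 1.59, camera adjusted p = 1.28e-06 (0.539 with an estimated correlation). Schwann cell genes differed upward in 8 of 10 cases (8 over the list alone), with a median of 2.37, camera adjusted p = 1.03e-05 (0.210 with an estimated correlation). The largest positive interactions were in Lrrc14b (7.67 ± 1.71), Myh4, Pvalb (6.68 ± 1.28), the muscle actinin gene Actn3 (6.30 ± 1.2) and Plcd4 (6.30 ± 1.21). The largest negative were in keratin-associated genes whose counts of 0 leave no size, among them Krtap14 and Krtap19-9b (adjusted p = 0.00632 and 0.00497). With the hair score as a covariate edgeR called 0 genes for the interaction (1499 at an unadjusted p under 0.05), and with the muscle score 3. Given the hair score the collagen and fibroblast (0.447), hair (0.227), skeletal muscle (0.0508), endothelial (0.0508), melanocyte (0.178) and mitochondrially encoded (0.530) lists were not called. That score added cornified layer (0.000212) as higher and cytokine (0.00378), chemokine (0.00506), IL-6 and STAT3 (0.00407), wound repair (0.00197), oxidative stress (0.000749), neutrophil (1.90e-07) and erythroid cells (0.00934) as lower. Given the muscle score the collagen and fibroblast (0.249), cholesterol (0.223), skeletal muscle (0.414) and adipocyte (0.152) lists were not called, and the mitochondrially encoded (0.000559) list was called in the other direction. That score added cornified layer (2.11e-11), basal keratinocyte (0.0280) and T and NK cell (0.0237) as higher and oxidative stress (0.00692), neutrophil (0.00328) and erythroid cells (2.35e-06) as lower. List calls also ended for mitochondrially encoded (0.992) with uniquely placed reads. Other lists passed as well, oxidative stress as lower with no filter (0.0188) and thinning (0.0393), and immediate early as lower with no filter (0.0298), the replicate number as a block (0.0337) and thinning (0.0482). Without a covariate DESeq2 called 5414 and limma-voom 4713.

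**Figure D3:**
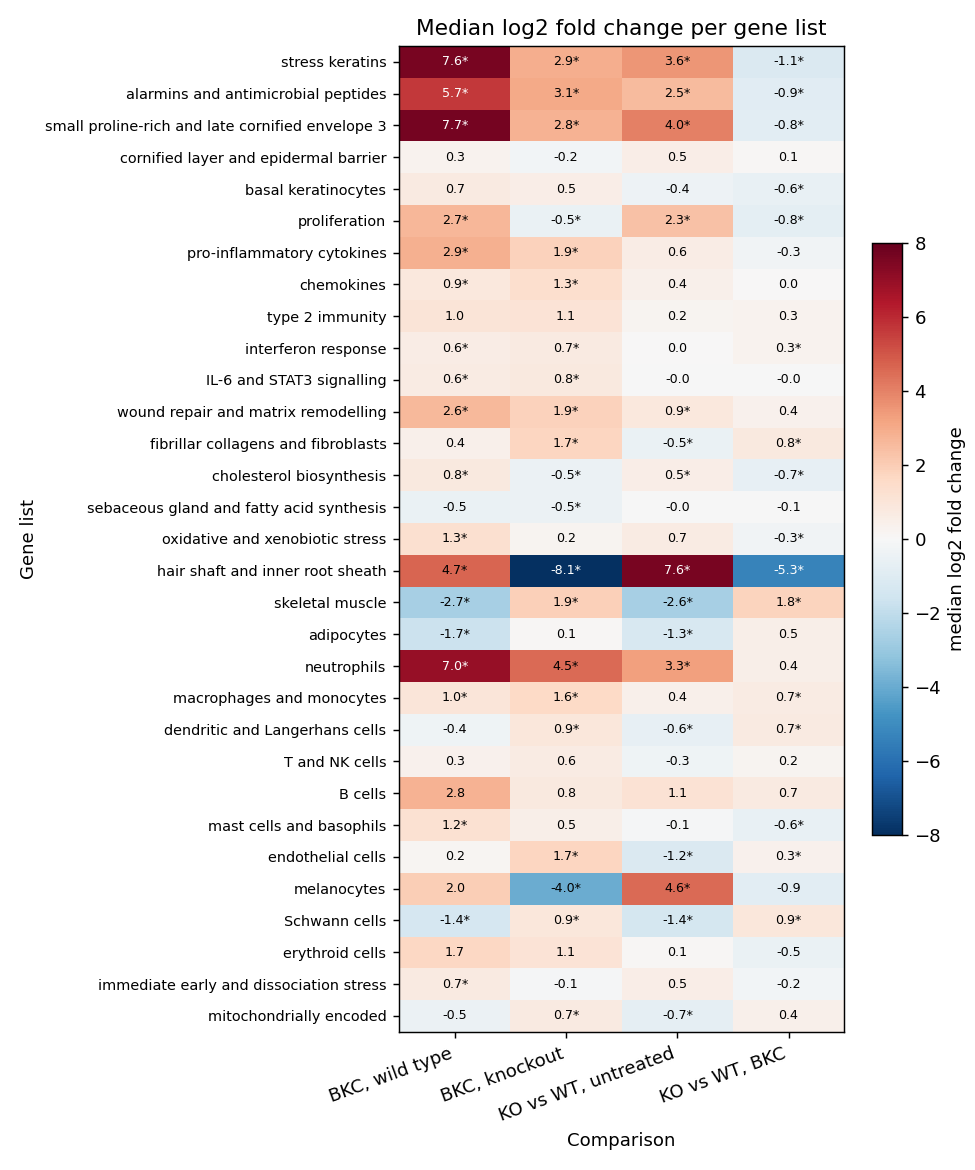
Median log2 fold change of each of the 31 gene lists in 4 comparisons, with genes at 0 reads set to their bound. Numbers are medians, colours end at 8 on the log2 scale in both directions, and a star marks a camera adjusted p under 0.05, none of which held with an estimated correlation. Hair genes have medians of -8.05 for BKC in labelled knockout and 7.62 for labelled knockout against wild type in untreated skin.

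Between the BKC effects in the genotypes, which share no library, 599 genes were higher in both and 217 lower in both, where independent lists of these sizes would share 378 and 287. Another 457 were higher in wild type and lower in labelled knockout, and 189 the reverse, against 383 and 283 for independent lists. Across the 13833 genes, which are not independent replicates, Pearson's r of the fold changes was -0.137 and Spearman's rho -0.0675.

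Genes near Il6 were compared with the rest because a knockout allele can carry neighbouring DNA of the strain it was made in. Of 199 tested genes within 20 Mb of Il6 on chromosome 5, 57 were called between genotypes in untreated skin, against 4069 of 13634 elsewhere (odds ratio 0.944, 95% interval 0.680 to 1.29, one-sided Fisher's exact test, p = 0.669). In BKC-treated skin AI506816 was the only call among the 199 genes, against 1 of 13634 elsewhere (one-sided Fisher's exact test, p = 0.0286). This p rests on that gene, and without wild-type replicate 3 the exact test gave p = 0.880, with 12 of 200 and 1111 of 13929 called.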

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

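The tests of the muscle score, of the placing of left-out libraries, of junction and intron reads of Il6 and of the mean of both genotype contrasts, as well as the fit with uniquely placed reads, were chosen only after the result was seen.

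The BKC effect differed between genotypes in 50 of 72 genes followed here and in 14 of 31 lists (edgeR quasi-likelihood interaction and camera, Benjamini-Hochberg adjusted), where these 72 include genes picked for large fold changes. Over all genes it was 4839 of 13833. Of the 4839, 3494 (72.2%) were also called between untreated genotypes, but both contrasts share the untreated libraries. Lists of these sizes from 10 simulations without any difference shared 2446 to 2499, which does not give the part of the real overlap due to these libraries. A differing response to BKC is thus not shown apart from a differing untreated state. Among epidermal genes the interaction (log2) was Krt6b (-8.06), Krt16 (-5.81), Krt6a (-3.57), Krt17 (-2.79), Krt14 (-1.81), Sprr1b (-7.66). For inflammation and repair it was S100a8 (-4.87), S100a9 (-5.07), Slpi (-3.59), Saa3 (-3.71), Il1b (-4.88), Areg (-3.89), Tnc (-2.34). Proliferation, stress and lipid genes stood at Mki67 (-3.66), Birc5 (-3.29), Slc7a11 (-6.17), Idi1 (-2.59), Elovl3 (-4.91). Other genes with a lower effect were AI506816 (-3.04), Fcer1a (-5.64), Krt71 (-12.23), Tyrp1 (-6.74). The effect was higher in labelled knockout for Skint7 (4.05), Angptl7 (4.50), Adh6a (3.21), Retnla (4.28), Prx (3.72), Tie1 (1.77), Vwf (2.31). Muscle-related genes stood at Pvalb (6.68), Acta1 (4.24), Lrrc14b (7.67), Myh4 (7.51), Dusp26 (5.79), Mstn (6.27), Actn3 (6.30), Plcd4 (6.30). For genes with groups at 0 to 3 reads the adjusted p of the interaction was Sprr2i (0.0257), Tmprss11b (0.0331), Sprr2a1 (0.0143), Cxcl2 (0.0278). Keratin-associated genes had Krtap14 (0.00632), Krtap19-9b (0.00497), Krtap19-5 (0.00461), Krtap19-2 (0.00431), Krtap6-2 (0.00501), Krtap19-1 (0.00424), Krtap19-9a (0.0230), Krtap19-4 (0.00441), Krtap19-3 (0.00320). Camera adjusted p for lists with a lower effect in labelled knockout were stress keratins (0.00107), alarmins and antimicrobial peptides (0.00108), small proline-rich and late cornified envelope 3 (2.96e-08), proliferation (1.68e-13), cholesterol biosynthesis (1.28e-06), hair shaft and inner root sheath (1.68e-13), melanocytes (0.00308). Lists with a higher effect had fibrillar collagens and fibroblasts (0.00334), skeletal muscle (2.03e-08), adipocytes (0.00126), dendritic and Langerhans cells (0.000386), endothelial cells (1.28e-06), Schwann cells (1.03e-05), mitochondrially encoded (0.00683). None of these calls held with an estimated correlation (lowest adjusted p = 0.210). Of 200 splits of the genotype labels within treatments 60 were drawn. Only the real one, 1 of 60, gave as many genes (4839, highest other 3389). Tissue makeup stays open here. Single left-out libraries ended the interaction call of Il1b (adjusted p = 0.0627 and 0.0687 without wild-type untreated replicate 1 or 3, 0.0516 without labelled-knockout untreated replicate 2, 0.0505 without wild-type BKC replicate 1 and 0.0535 without labelled-knockout BKC replicate 3). They also ended those of Cxcl2 (0.0678, 0.0607 and 0.0711 without wild-type untreated replicate 1, 2 or 3, 0.0539 without labelled-knockout untreated replicate 2, 0.0573 without wild-type BKC replicate 1 and 0.0508 without labelled-knockout BKC replicate 3), Sprr2i (0.112 without labelled-knockout untreated replicate 2) and Krtap19-9a (0.241 without wild-type BKC replicate 1). Tmprss11b was lost as well (0.0597, 0.0551 and 0.0605 without wild-type untreated replicate 1, 2 or 3, 0.127 without labelled-knockout untreated replicate 2 and 0.0551 and 0.0634 without labelled-knockout BKC replicate 2 or 3). Saa3 was no longer called at 0.0810, 0.0583 and 0.0636 without wild-type untreated replicate 1, 2 or 3, 0.0727 without labelled-knockout untreated replicate 1 and 0.0537 and 0.0609 without labelled-knockout BKC replicate 1 or 3. Krt14 was no longer called at 0.0768 and 0.0688 without wild-type untreated replicate 1 or 3, 0.0585 and 0.0572 without labelled-knockout untreated replicate 2 or 3, 0.0711 and 0.0815 without wild-type BKC replicate 1 or 2 and 0.0610 without labelled-knockout BKC replicate 3, nor Adh6a at 0.0509, 0.0568 and 0.0523 without wild-type untreated replicate 1, 2 or 3, 0.0622 and 0.0646 without labelled-knockout untreated replicate 1 or 3, 0.0844 and 0.0505 without wild-type BKC replicate 2 or 3 and 0.1 without labelled-knockout BKC replicate 1.

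The genotypes differed in 4126 genes in untreated skin, and the other 9 splits of these 6 libraries gave at most 0, but 10 splits are too few for a share under 0.05 (1 of 10). Reads shared between similar genes are argued against as the cause, since 3947 genes were called with uniquely placed reads. The hair growth phase of the skin piece may contribute, as the fold changes of called genes went with their slope on the hair score within the BKC groups (r = 0.750 across genes, reached by 7 of 36 orderings of the score, at most 0.791), so it stays open. The amount of muscle in the piece stays open as well (r = -0.803, 3 of 36 orderings, most extreme -0.811), where the first version of this test had named the wrong sign. Genotype itself, the groups' own processing of the tables and these tissue differences cannot be told apart, because each follows the groups.

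The Il6 intron had 24 reads in the untreated libraries labelled knockout and 0 in untreated wild type, a signal in a column that no comparison above uses, and 46 against 6 after BKC. Wrong labels of single libraries were tested by placing each with the gene that best separated the other 11, each time AI506816. All 12 lay on their own side, by at least 1.13 (log2 CPM) from the midpoint. AI506816 parted all 12 by label, so this is no new test. DNA or unspliced RNA as the only source is argued against by the 33.3% of Il6 exon reads in labelled-knockout libraries that span a junction (44.2% in wild type). An altered transcript from the targeted allele stays open, since the higher intron reads in labelled knockout (one-sided exact permutation test, p = 0.0025) are the observation itself and no test of it. An exchange of the genotype labels as a whole stays open, and the gene was chosen before its reads were seen.

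Genes within 20 Mb of Il6 were weighed for DNA of another strain carried with the knockout allele, which the untreated comparison leaves open (one-sided Fisher's exact test, p = 0.669, odds ratio 0.944, 95% interval 0.680 to 1.29). This odds ratio was 1.22 and 1.26 without wild-type replicate 1 or 3 and 1.32, 1.06 and 1.39 without labelled-knockout replicate 1, 2 or 3 (exact test, lowest p = 0.0584). In BKC-treated skin the same exact test gave p = 0.0286 from a single gene, AI506816, and 0.880 without wild-type BKC replicate 3. In the mean of both genotype contrasts 2 of 11 called genes lay in the window (exact test, p = 0.0104), AI506816 (-5.65 ± 0.32 SE) and Abhd1 (2.47 ± 0.30), the latter chosen after its values were seen and with 89.6% of its exons overlapped by Preb. A strain variant near these genes may thus be present, which the tables of counts cannot test further.

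For BKC the real split, 1 of 10, was the only one to give as many genes in wild type (5117, highest other 0) and in labelled knockout (3599, highest other 0), where 10 splits are too few for a share under 0.05. In wild type 3 of the other splits part as many same-number pairs as the real one, 3, and gave 0 as the rest did. Between genotypes after BKC 2 of 10 splits gave as many genes as the real one, which gave 2, and the highest other gave 1268. That split set wild-type replicates 1 and 2 with labelled-knockout replicate 1 against the rest, as the muscle share of these libraries does, which points to a structure of the samples.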

How the results depend on the processing

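The covariate, unique-read, exon-length and thinning settings and the mean of both genotype contrasts were chosen only after the result was seen. Numbers of called genes are given in the order BKC in wild type, BKC in labelled knockout, genotype untreated, genotype after BKC and interaction. Other scalings, no filter, thinning, unique reads, all exon lengths and the replicate block left each number within 1.5 times of 5117, 3599, 4126, 2 and 4839, without showing that the same genes were called. With the hair score as a covariate they were 3321, 0, 0, 1 and 0, and with the muscle score 1948, 2348, 192, 2 and 3, where the scores themselves follow the groups, so the covariate takes up part of each contrast. A fold of at least 2 left 2827, 2186, 2306, 2 and 3592, by its construction. For genotype after BKC, DESeq2 called 967, limma-voom 1 and a fit of only the 6 libraries compared 0, and the cause was not tested. Leaving out single libraries gave 2917 to 5423, 1364 to 5067, 1736 to 5116, 1 to 1123 and 3323 to 5950. The exact flank test ranged from p = 0.0584 to 0.632 untreated and from 0.0142 to 0.880 after BKC (without wild-type BKC replicate 3), and was 0.686 and 0.0243 at 10 Mb (0.00759 for the mean of both contrasts).

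With the hair score as a covariate the camera direction (adjusted p) reversed for BKC in labelled knockout in skeletal muscle (0.00600). With the muscle score it reversed in mitochondrially encoded for genotype untreated (0.0201) and the interaction (0.000559). With the hair score the log2 fold change of Krt71 reversed sign for BKC in labelled knockout (1.82), genotype untreated (-0.38) and the interaction (1.26). With the muscle score signs reversed for BKC in wild type in Krtap6-1 (-7.77), Krt82 (-6.53), Padi3 (-0.40), Flg (-1.03) and Acta1 (0.41). They also reversed for genotype untreated in Krtap19-2 (-4.04), Krtap19-3 (-3.0) and Acta1 (0.29), and for the interaction in Acta1 (-0.17). None of these fold changes passed the test with the score (adjusted p from 0.266 to 0.949), so no change in the other direction is shown. The scores are made from the hair and muscle lists, so a list or member changed under its own score is no independent test. The scores also follow the groups, and other causes were not tested. For genes with a group at 0 to 3 reads only the test was compared.

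Values of named genes under the alternatives fell out as follows. For BKC in wild type 2298 kept direction and side of the threshold, 180 lost and 28 gained the call, and 5 reversed. For BKC in labelled knockout 581 kept direction and side of the threshold, 60 lost and 4 gained the call, and 1 reversed. For genotype untreated 426 kept direction and side of the threshold, 65 lost and 6 gained the call, and 4 reversed. For genotype after BKC 1283 kept direction and side of the threshold, 11 lost and 48 gained the call, and 0 reversed. For the interaction 1187 kept direction and side of the threshold, 164 lost and 3 gained the call, and 2 reversed. Another pseudocount does not apply to counts. With the replicate number as a block the calls of Flg for BKC in wild type (adjusted p = 0.0513) and Elovl3 between genotypes after BKC (0.0713) were lost. Its effect on lists is given in the report, and it changed no other call of a gene printed here. At this depth 2-fold changes were recovered in 4.04% to 35% of simulated genes, so an uncalled gene is not shown to be unchanged.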

Other observations

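Tests were fixed beforehand, but genes were picked by adjusted p. In wild-type skin 2 genes of epidermal immune cells fell after BKC, which their whole lists do not show. Cd207, the langerin gene of Langerhans cells, went from 12.0 ± 5.42 to 1.21 ± 0.283 CPM (log2 fold change -3.29 ± 0.82 SE, adjusted p = 0.0121, edgeR quasi-likelihood test, n = 3 mice per group), and Trdc, the constant region of the delta T cell receptor, from 9.55 ± 0.704 to 1.86 ± 1.02 (log2 fold change -2.36 ± 0.56, adjusted p = 0.00985), with 39.2% of its reads uniquely placed. The dendritic and Langerhans cell list did not pass there (median log2 fold change -0.37, camera adjusted p = 0.577, adjusted p = 0.895 with an estimated correlation), nor did the T and NK cell list (median log2 fold change 0.33, camera adjusted p = 0.839, adjusted p = 0.947 with an estimated correlation). In labelled-knockout skin Cd207 and Trdc stood at -0.88 ± 0.78 and -1.35 ± 0.57 (adjusted p = 0.411 and 0.0987), and the interaction was not past the test (adjusted p = 0.119 and 0.343). Retnla, a gene of alternatively activated macrophages, fell in wild-type skin from 132 ± 83.6 to 3.89 ± 2.27 CPM (log2 fold change -5.05 ± 0.77, adjusted p = 0.00129). Fcer1a, the alpha chain of the high-affinity IgE receptor, rose there from 0.271 ± 0.0704 to 5.87 ± 1.71 CPM (log2 fold change 4.29 ± 0.67, adjusted p = 0.00138). In labelled-knockout skin 5 of 15 dendritic and Langerhans cell genes rose after BKC (5 adjusted over the list alone, median log2 fold change 0.92). Their camera adjusted p was 2.63e-05 (0.455 with an estimated correlation). Interferon response genes rose in 3 of 25 (1 over the list alone, median 0.73), against 1786 of all 13833 genes. That list's camera adjusted p was 0.000144 (0.549 with an estimated correlation).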
